A study of Arabidopsis thaliana with 6 samples.

How the data were processed

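The series holds 6 RNA-seq libraries of whole Arabidopsis thaliana seedlings of the insertion line ahl13-1, 3 controls and 3 sprayed with Pst hrcC. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples. Per the labels' protocols, total RNA of whole seedlings was made into mRNA libraries and sequenced as paired ends. The submitters' processing notes name FastQC, TopHat2 2.1.1, Cufflinks 2.2.1 and the TAIR10 build. The annotation, the library's strand and the settings of each step are not given in the sources used here.

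The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled by the mapped fragments of the library) with 27371 gene identifiers and 1 column per library. The values were used as deposited, without rescaling. Gene symbols came from gene lists written for this work and from a RefSeq table of the TAIR10.1 assembly, in which 26703 of the identifiers (97.6%) were found; 668 were not and kept their identifier. Since that assembly is not the build named in the notes, it was used only for names, product names and spliced lengths, and no coordinates are given.

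FPKM holds no counts, so depth was not known directly. Values of genes near 1 fragment in control replicate 1 change between libraries in whole steps, and the size of the step gave the relative depth of each library. In the 5 other libraries between 53.4% and 78.7% of such ratios lay on a whole step within 0.015 on the log2 scale, so whole reads were not recovered and no count model was used. On simulated data the step size was recovered before it was used. The simulated genes all held 1 fragment in the reference library, which the real ones need not. The simulation therefore does not give the error of the depths. Values of exactly 0 occur for genes of general function too, so a gene without signal is described as listed at 0. Very short genes carry much of the summed FPKM: the 518 genes under 300 bp held from 23.2% to 69.0% of it.

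The test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes with a mean of at least 1 FPKM over the 6 libraries were tested (16923; 10448 were left out) on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using an intensity-dependent prior variance, treatment as the only term, 4 residual degrees of freedom and two-sided tests. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Errors are SD over 3 libraries for levels and SE from limma for log2 fold changes. With 5 simulated sets of 16923 genes in which 200 were changed, this test recovered 43.6% of 2-fold, 86.0% of 4-fold, 94.4% of 8-fold and 94.4% of 16-fold changes, with 9.8 false calls among 169 on average. Simulated values were independent normal draws with each gene's estimated spread and no structure shared within libraries. These rates therefore do not give the power in the real libraries, where the smallest log2 change called was 1.28.

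Lists with at least 5 tested members were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists; fry and an estimated correlation were alternatives. The 24 lists hold 556 distinct genes: pattern-triggered signalling, WRKY factors, salicylic acid, jasmonate, camalexin and indole glucosinolates, aliphatic glucosinolates, ethylene, abscisic acid and cold or drought, nuclear photosynthesis, phenylpropanoids, flavonoids, cysteine-rich receptor-like kinases, heat shock, hypoxia, iron deficiency, phosphate starvation, clock, auxin, senescence, cell cycle, root markers, seed markers, the AT-hook motif family and reference genes. No call of camera held with an estimated correlation. Of the 11 lists called, fry called jasmonate (adjusted p = 0.0107) and camalexin and indole glucosinolates (adjusted p = 0.0361). Fry asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes.

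Named genes are AHL13, the 5 highest and 5 lowest log2 fold changes among changed genes whose groups do not overlap, and the members with the smallest p of each list (3 for the 6 defence lists, 2 for the others); the text gives those that carry a comparison. Other genes are said to have been chosen after their values were seen. Shares of summed FPKM were compared with two-sided exact permutation tests, whose smallest p is 0.1 for 3 against 3.

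The replicate numbers are shared by the groups. The deviations of same-numbered libraries from their group means correlated at 0.43, 0.17 and 0.13 across genes for replicates 1, 2 and 3. Each is over 0.1, so the numbers were taken to pair the libraries. This comes from the data and not from the labels, and only the replicate 1 pair stands out. Control replicate 3 correlated best with Pst hrcC replicate 2 (0.21), and control replicate 2 correlated with Pst hrcC replicate 3 at 0.07. Deviations within a group cancel out, so the rule cannot tell how replicates 2 and 3 pair. No pair of libraries held identical values throughout. The fit without the block stays the main one, and values with the replicate number as a block are given where they change a call.

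The alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, rescaling over nuclear genes, no variance trend, a robust prior variance, the replicate block, each library left out, a 2-fold minimum and adjusted p under 0.01 and 0.1. Chosen after seeing the data were leaving out the replicate 1 pair, a term for replicate 1, limma array weights and leaving out genes under 300 bp. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for reading and drawing.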

Results

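The study measured transcript levels by paired-end RNA sequencing in Arabidopsis thaliana ahl13-1, an insertion line in AHL13. AHL13 belongs to the AT-hook motif nuclear localized proteins, a plant family that binds AT-rich DNA. Whole seedlings aged 14 days were either controls (3 libraries) or sprayed with Pst hrcC at an optical density of 0.002 for 24 hours (3 libraries). Pst hrcC is a strain of Pseudomonas syringae pv. tomato without a working type III secretion system, which presents microbial patterns to the plant and delivers no effectors through that system. The comparison cannot tell a response to those patterns from one to other products of the strain. The series title places AHL13 in immunity triggered by such patterns, so the comparison asks which transcripts the treatment changed in this mutant. The labels do not say what the control seedlings received. Wild-type libraries belong to another series and are not analysed here, so no value is a difference between genotypes. Values are FPKM, and fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values.

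The 6 libraries differed in depth and in composition. Read from the steps of the lowest values, the depth of control replicates 2 and 3 was 4.89 and 2.86 times that of control replicate 1, and that of Pst hrcC replicates 1, 2 and 3 was 4.55, 3.81 and 0.82 times. Summed FPKM ran from 550770 in control replicate 2 to 2156600 in control replicate 3. A single transcript of 102 bp, AT2G01021, took between 15.6% and 52.0% of that sum. Chloroplast genes took 4.56% ± 4.23 (SD, n = 3) in controls and 12.6% ± 1.18 (SD, n = 3) after Pst hrcC, with 0.239% in control replicate 2 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). Few genes carry that share, so it is not read as a change of chloroplast RNA. ATCG00690 was at 68298 FPKM in control replicate 1 and listed at 0 in every other library. ATCG00630 was at 0, 0 and 101429 FPKM in controls and 72919, 16198 and 43477 FPKM after Pst hrcC. The 10 most abundant genes took 62.3% ± 20.8 (SD, n = 3) in controls and 63.5% ± 12.7 (SD, n = 3) after Pst hrcC (two-sided exact permutation p = 0.9).

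AHL13 (AT4G17950), the gene carrying the insertion, was read at 2.32, 2.17 and 2.47 FPKM in the controls and at 1.98, 2.43 and 2.08 FPKM after Pst hrcC. The group means of 2.32 ± 0.15 and 2.16 ± 0.24 FPKM (SD, n = 3 each) gave p = 0.4 in a two-sided exact permutation test, which can reach 0.1 at the lowest, and the log2 fold change was -0.07 ± 0.12 (SE, limma adjusted p = 1.00). Without a wild type among the libraries, and with no position of the insertion given in the sources used here, these values do not check the mutation.

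After Pst hrcC far more transcripts were higher than lower in ahl13-1. Of 16923 genes tested, 49 changed, and 48 of these rose. The jasmonate list held 13 of the 49, and 33 belonged to no list. The lists were written for this work and need not hold every gene of their theme. The 33 are therefore not a count of genes outside the jasmonate response. The single gene that fell was NAS2 (AT5G56080), a nicotianamine synthase of iron transport, from 17.3 ± 2.38 to 2.02 ± 1.16 FPKM (SD, n = 3 each). Its log2 fold change was -2.66 ± 0.27 (SE, limma adjusted p = 0.0363, and 0.0534 with the replicate number as a block). It no longer passed without control replicates 1, 2 or 3 (limma adjusted p = 0.0663, 0.217 and 0.190) or Pst hrcC replicates 2 or 3 (limma adjusted p = 0.178 and 0.119).

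Among the genes named by rule, NATA1 (AT2G39030), an acetyltransferase that acts on ornithine, was listed at 0 in all 3 controls and at 99.1, 174 and 283 FPKM after Pst hrcC (limma adjusted p = 0.00356). FAMT (AT3G44860), a methyltransferase of farnesoic acid, rose from 0.243 ± 0.173 to 82.8 ± 50.4 FPKM (SD, n = 3 each), a log2 fold change of 5.86 ± 0.50 (SE, limma adjusted p = 0.0273). NATA1 passed without any 1 library, while FAMT did not pass without control replicates 1, 2 or 3 (limma adjusted p = 0.0547, 0.163 and 0.143) or Pst hrcC replicates 2 or 3 (limma adjusted p = 0.178 and 0.0667). Chlorophyllase CLH1 (AT1G19670) and the beta-glucosidase BGLU18 (AT1G52400), chosen after their values were seen, rose by 4.59 ± 0.32 and 3.84 ± 0.35 on the log2 scale (SE, limma adjusted p = 0.0180 and 0.0273). In all 49 changed genes the 3 treated values lay on one side of the 3 control values. Selection by a small p makes this likely, so it adds no support to the calls. Over all tested genes, 7.7% lay wholly above and 3.6% wholly below, where chance gives 5% each way. At an unadjusted p under 0.05, 876 genes were higher and 276 lower.

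With the replicate number as a block 47 genes changed (45 higher, 2 lower), of which 26 were among the 49. The number of changed genes depended on single libraries. In the fit without the block it was 19, 2 and 3 without control replicates 1, 2 and 3, and 180, 2 and 3 without Pst hrcC replicates 1, 2 and 3. Without the replicate 1 pair, whose clock genes differed from the other pairs, it was 182 (173 higher, 9 lower), of which 43 were among the 49. After rescaling over nuclear genes alone it was 101, with 79 higher and 22 lower, of which 23 were among the 49. That setting divides by summed nuclear FPKM, much of which very short genes carry. Genes under 300 bp held from 23.2% to 69.0% of all summed FPKM, so calls lost under it may reflect those genes. In limma 309 genes had an unadjusted p under 0.05 in that setting, against 1152 in the main fit.

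Of 38 tested members of the jasmonate list, 13 rose, none fell and 25 did not pass; adjusted over the list alone, 35 rose and none fell. The 13 span the pathway: LOX2, AOC1 and OPR3 encode enzymes of jasmonate synthesis, JAZ6, JAZ7, JAZ8 and JAZ9 encode repressors that jasmonate itself induces, ST2A encodes a sulfotransferase of hydroxyjasmonate, and TAT3, CORI3 and the PDF1.2 defensins are response genes. Those outside the PDF1.2 copies and TAT3 were chosen after their values were seen. With the replicate block 9 of the list rose: 7 of the 13, and JAZ2 and ANAC055 (limma adjusted p = 0.0473 and 0.0299). Besides PDF1.2a and LOX2, CORI3, OPR3, JAZ8 and ST2A did not pass with the block (limma adjusted p = 0.0537, 0.0611, 0.0611 and 0.0799). PDF1.2c (AT5G44430) stood at 0.510 ± 0.379 FPKM in controls and 160 ± 62.6 FPKM after Pst hrcC (SD, n = 3 each), a log2 fold change of 6.69 ± 0.35 (SE, limma adjusted p = 0.00356). PDF1.2a (AT5G44420) was at 1.73, 0 and 3.6 FPKM in controls and 247, 418 and 150.2 FPKM after treatment (limma adjusted p = 0.0273, and 0.0524 with the replicate block). PDF1.2b (AT2G26020) was at 0, 0.398 and 2.19 FPKM in controls and 152, 77.5 and 59.2 FPKM after treatment (limma adjusted p = 0.0273). TAT3 (AT2G24850), a tyrosine aminotransferase, rose by 3.39 ± 0.25 on the log2 scale (SE, limma adjusted p = 0.0204). LOX2 (AT3G45140) rose by 4.77 ± 0.46 (SE, limma adjusted p = 0.0361, and 0.0534 with the replicate block). The PDF1.2, AOC and VSP copies are close paralogs, so the division of reads among them is uncertain.

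**Figure D1:**
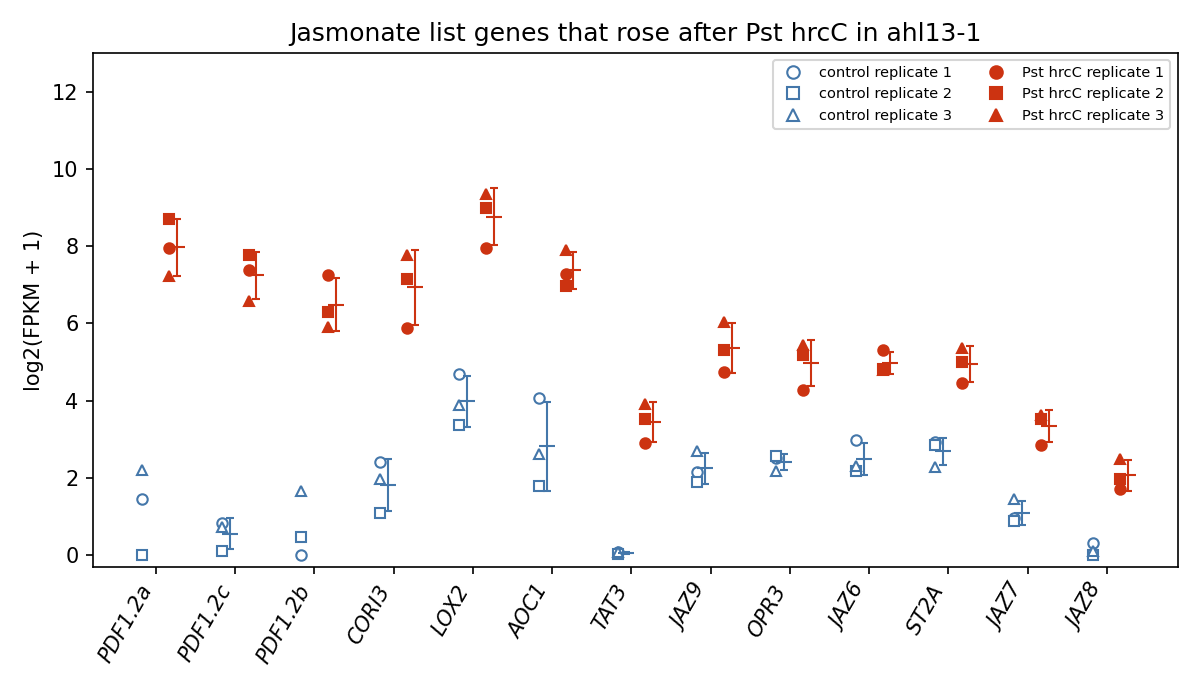
Level of each of the 13 jasmonate list genes that rose, as log2(FPKM + 1), in the 3 control libraries (open blue symbols) and the 3 Pst hrcC libraries (filled red symbols), with the mean and SD of each group in which no library is listed at 0. In all 13 genes the 3 treated libraries lie above the 3 controls.

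The median log2 change of the jasmonate list was 2.39 (quartiles 1.17 and 3.41), and 35 of the 38 members were higher in all 3 same-numbered pairs. The camera test with its preset correlation called the list higher (adjusted p = 1.3e-54), and the call was lost with an estimated correlation (adjusted p = 0.113 with an estimated correlation). The pair medians were 1.74, 2.64 and 3.00 for replicates 1, 2 and 3. VSP1 (AT5G24780), a vegetative storage protein chosen after its values were seen, did not pass (limma adjusted p = 0.191): it was at 9.04, 7.13 and 7.71 FPKM in controls and at 46.4, 536 and 784 FPKM after treatment. In the same libraries the 17 tested root markers had a median log2 change of 0.34, with 0.12, 0.04 and 1.09 in the 3 pairs. In place of 13, the number that rose was 7, 1 and 1 without control replicates 1, 2 and 3, and 24, 1 and 1 without Pst hrcC replicates 1, 2 and 3, while the list median stayed between 2.14 and 2.74. It was 25 without the replicate 1 pair, 24 with a term for replicate 1, 33 with array weights, 7 with a pseudocount of 5 and 1 with no filter on low values. PDF1.2c passed without any 1 library. PDF1.2a, PDF1.2b and TAT3 did not pass without control replicate 2 (limma adjusted p = 0.112, 0.169 and 0.112), control replicate 3 (0.0820, 0.0513 and 0.103), Pst hrcC replicate 2 (0.178, 0.178 and 0.162) or Pst hrcC replicate 3 (0.101, 0.101 and 0.0560), nor PDF1.2a without control replicate 1 (0.0592).

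In the aliphatic glucosinolate list, which covers methionine-derived defence compounds, none of 21 members passed in limma over all genes (20 were higher at an unadjusted p under 0.05), and 20 rose adjusted over the list alone. Adjusted over the list alone, 13 rose after rescaling over nuclear genes. Over all genes, 2 members passed without control replicate 1, 3 without Pst hrcC replicate 1, 5 without the replicate 1 pair or with a term for replicate 1 and 16 with array weights. After rescaling over nuclear genes and among genes of 300 bp or more 2 passed, and 1 passed with a pseudocount of 0.1. All 21 were higher in all 3 pairs, with a median log2 change of 1.76 and pair medians of 0.90, 1.61 and 2.77. BCAT4 (AT3G19710), the aminotransferase that opens the chain elongation of methionine, was at 3.86 ± 2.51 and 27.2 ± 6.29 FPKM (SD, n = 3 each), a log2 difference of 2.63 ± 0.36 (SE, limma adjusted p = 0.0548). GSTF11 (AT3G03190) was at 3.45 ± 0.66 and 23.0 ± 11.4 FPKM (SD, n = 3 each; limma adjusted p = 0.0604), and the sulfotransferase SOT18 (AT1G74090) at 25.3 ± 0.61 and 72.9 ± 20.2 FPKM (SD, n = 3 each; limma adjusted p = 0.0695). The list was called higher by camera (adjusted p = 2.1e-27), a call lost with an estimated correlation (adjusted p = 0.191 with an estimated correlation) and with fry (adjusted p = 0.0567).

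The list of camalexin and indole glucosinolate metabolism had 1 gene of 24 that rose, none that fell and 23 that did not pass; adjusted over the list alone, 13 rose. SUR1 (AT2G20610), the C-S lyase shared by glucosinolate routes, rose from 7.60 ± 0.94 to 20.7 ± 3.63 FPKM (SD, n = 3 each), a log2 fold change of 1.33 ± 0.17 (SE, limma adjusted p = 0.0498, and 0.0623 with the replicate block). With the block 1 gene of the list rose, the methyltransferase IGMT1 (AT1G21100), chosen after its values were seen (limma adjusted p = 0.0473 with the replicate block, and 0.200 without it). CYP71A13 (AT2G30770), an enzyme of camalexin synthesis with a close paralog, was at 0.385 ± 0.211 and 2.90 ± 0.87 FPKM (SD, n = 3 each; limma adjusted p = 0.0618). UGT74B1 (AT1G24100) was at 23.1 ± 1.18 and 60.4 ± 15.3 FPKM (SD, n = 3 each; limma adjusted p = 0.0806). The median log2 change was 0.75, with pair medians of 0.85, 0.66 and 1.21 (camera adjusted p = 1.1e-13; adjusted p = 0.142 with an estimated correlation). Adjusted over the list alone, 6 and 7 rose without control replicates 2 and 3, and 8 without Pst hrcC replicate 2. After rescaling over nuclear genes, 1 of 25 tested members rose adjusted over the list alone and none over all genes, while the median was 0.71. Over all genes 11 rose with array weights, 3 without the replicate 1 pair, and 2 with a term for replicate 1 and among genes of 300 bp or more. Without the replicate 1 pair 1 fell adjusted over the list alone. None rose over all genes under median-of-ratios scaling or quantile normalization, with no filter on low values, without a variance trend or with a pseudocount of 5. SUR1 did not pass without control replicates 1, 2 or 3 (limma adjusted p = 0.0903, 0.313 and 0.244) or Pst hrcC replicates 1, 2 or 3 (limma adjusted p = 0.0541, 0.189 and 0.169), and of these only the fit without Pst hrcC replicate 1 had another member that rose. The root markers, with a pair median of 1.09 in replicate 3, were higher in the pair in which both glucosinolate lists had their highest median.

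Of 23 salicylic acid genes none passed in limma over all genes (7 were higher at an unadjusted p under 0.05), and 3 rose adjusted over the list alone. These were PR5 (AT1G75040), a thaumatin-like protein, at 4.15 ± 1.09 and 10.5 ± 0.68 FPKM (SD, n = 3 each; limma adjusted p = 0.0778), PR2 (AT3G57260), a glucanase, at 1.84 ± 0.75 and 15.4 ± 13.2 FPKM (SD, n = 3 each; limma adjusted p = 0.315), and ACD6 (AT4G14400) at 2.53 ± 0.79 and 5.35 ± 1.13 FPKM (SD, n = 3 each; limma adjusted p = 0.334). The 3 were 1 without control replicate 2, 2 without control replicate 3, 5 without Pst hrcC replicate 1, 1 without Pst hrcC replicate 2 and 2 without Pst hrcC replicate 3. Adjusted over the list alone, 1 rose under quantile normalization, with a pseudocount of 5 and with no filter on low values, 8 without the replicate 1 pair and 10 with array weights. Over all genes 6 rose with array weights, 2 without the replicate 1 pair and 1 without Pst hrcC replicate 1. PR1 (AT2G14610), the usual marker of salicylic acid signalling and chosen after its values were seen, was at 1.94, 0.730 and 0 FPKM in controls and 5.74, 0.125 and 0 FPKM after treatment. The list's median log2 change was 0.33, with pair medians of 0.23, 0.29 and 0.48 (camera adjusted p = 6.9e-06; adjusted p = 0.240 with an estimated correlation).

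Among 21 WRKY transcription factors of defence, WRKY18 (AT4G31800) rose from 1.95 ± 0.58 to 7.43 ± 1.26 FPKM (SD, n = 3 each), none fell and 20 did not pass; adjusted over the list alone 1 rose, 5 with the replicate block and with a term for replicate 1, 4 without control replicate 3, 3 under median-of-ratios scaling and under quantile normalization, 2 with no filter on low values, and 0 after rescaling over nuclear genes and with a mean of at least 5 FPKM. With array weights 5 rose adjusted over the list alone and 2 over all genes. None rose over all genes in the other settings just named, without a variance trend or with a pseudocount of 0.1 or 5, except that 1 rose with a term for replicate 1. The log2 fold change of WRKY18 was 1.52 ± 0.19 (SE, limma adjusted p = 0.0490, and 0.0524 with the replicate block). It did not pass without control replicates 1, 2 or 3 (limma adjusted p = 0.0694, 0.234 and 0.244) or Pst hrcC replicates 2 or 3 (limma adjusted p = 0.204 and 0.175). WRKY45 (AT3G01970) and WRKY75 (AT5G13080) differed by 1.16 ± 0.30 and 0.54 ± 0.15 on the log2 scale (SE, limma adjusted p = 0.336 and 0.409). The median was 0.20, with pair medians of 0.55, 0.30 and 0.24 (camera adjusted p = 0.000249; adjusted p = 0.262 with an estimated correlation). Of 34 genes of pattern-triggered signalling, none passed in limma over all genes or adjusted over the list alone (5 were higher at an unadjusted p under 0.05). Adjusted over the list alone, 1 rose with the replicate block, without control replicate 1 and without Pst hrcC replicate 1, 1 rose and 1 fell with a term for replicate 1, and 1 rose with a pseudocount of 5 and with a mean of at least 5 FPKM. With array weights 3 rose adjusted over the list alone and 2 over all genes. The oxidase RBOHD (AT5G47910), source of the apoplastic oxidative burst, was at 4.61 ± 0.93 and 8.97 ± 0.80 FPKM (SD, n = 3 each; limma adjusted p = 0.180), the peptide receptor PEPR2 (AT1G17750) at 0.818 ± 0.043 and 1.87 ± 0.64 FPKM (SD, n = 3 each; limma adjusted p = 0.487), and the kinase MPK3 (AT3G45640) at 15.1 ± 3.83 and 23.0 ± 0.29 FPKM (SD, n = 3 each; limma adjusted p = 0.509). The median was 0.19, with pair medians of 0.28, 0.10 and 0.25 (camera adjusted p = 0.00248; adjusted p = 0.262 with an estimated correlation), and the call was lost without Pst hrcC replicate 1 (camera adjusted p = 0.0642) and after rescaling over nuclear genes (0.124).

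Flavonoid and anthocyanin genes were called higher as a list, with a median log2 change of 1.06 and pair medians of 0.47, 0.92 and 1.73. None of the 12 passed in limma over all genes (5 were higher at an unadjusted p under 0.05) and 2 rose adjusted over the list alone, UGT75C1 (AT4G14090) and UF3GT (AT5G54060), both glycosyltransferases of anthocyanins (camera adjusted p = 2.8e-05; adjusted p = 0.425 with an estimated correlation), and the call was lost with a mean of at least 5 FPKM (camera adjusted p = 0.0837). UGT75C1 was at 2.11 ± 0.82 and 6.04 ± 0.43 FPKM (SD, n = 3 each; limma adjusted p = 0.115). The 17 root markers were called higher (camera adjusted p = 0.00919; adjusted p = 0.415 with an estimated correlation), with none passing singly in limma (2 were higher at an unadjusted p under 0.05). That call was lost without control replicate 3 (camera adjusted p = 0.340), with a mean of at least 5 FPKM (0.120) and with array weights (0.136). PYK10 (AT3G09260), an abundant beta-glucosidase of roots, was at 130 ± 12.5 and 211 ± 65.2 FPKM (SD, n = 3 each; limma adjusted p = 0.664).

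Abscisic acid and cold or drought genes were called lower as a list, with a median of -0.26 over 18 members and pair medians of -0.20, -0.21 and -0.33 (camera adjusted p = 0.00229; adjusted p = 0.164 with an estimated correlation). The call was lost with a mean of at least 5 FPKM (camera adjusted p = 0.0837) and after rescaling over nuclear genes (0.124). None passed in limma over all genes (5 were lower at an unadjusted p under 0.05), and adjusted over the list alone NCED3 (AT3G14440), an enzyme of abscisic acid synthesis, fell, from 1.95 ± 0.33 to 0.753 ± 0.087 FPKM (SD, n = 3 each; limma adjusted p over all genes = 0.155). Nuclear photosynthesis genes had a median of -0.10 over 52 members and pair medians of -0.01, -0.01 and -0.29, and auxin genes a median of -0.18 over 19 members and pair medians of -0.11, -0.43 and 0.00; none of either list passed in limma, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 no photosynthesis gene was higher or lower, and 1 auxin gene was higher and 2 were lower. Both were called lower by camera (adjusted p = 0.00451 and 0.0124; adjusted p = 0.736 for each with an estimated correlation). The photosynthesis call was lost without control replicate 1 (camera adjusted p = 0.629) and after rescaling over nuclear genes (0.124), and its direction turned without Pst hrcC replicate 3 (camera adjusted p = 0.766). The direction of the auxin list turned without control replicate 1 (camera adjusted p = 0.885), and its call was lost without Pst hrcC replicates 2 and 3 (camera adjusted p = 0.263 and 0.244) under quantile normalization (0.0840) and with a mean of at least 5 FPKM (0.120).

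In the iron deficiency list NAS2 fell and 22 of 23 members did not pass; the list's median of 0.34 and its test differed in sign (camera adjusted p = 0.825). Of 13 ethylene genes 2 rose adjusted over the list alone, the transcription factors ORA59 (AT1G06160) and ERF2 (AT5G47220), at log2 differences of 1.64 ± 0.34 and 2.17 ± 0.47 (SE, limma adjusted p = 0.200 and 0.219), while the list's median of -0.08 and its test differed in sign (camera adjusted p = 0.868). Heat shock and phosphate starvation genes missed the threshold (camera adjusted p = 0.0508 for each); with the replicate block the heat shock list was called lower (camera adjusted p = 0.0367; adjusted p = 0.437 with the block and an estimated correlation). Heat shock genes were also called lower without control replicate 2 (camera adjusted p = 0.0199) or Pst hrcC replicates 2 or 3 (0.0425 and 0.0408), and phosphate starvation genes without control replicates 1 or 3 (0.0288 and 0.0251) or Pst hrcC replicate 1 (0.0142). Both lists were called lower with a pseudocount of 5 (camera adjusted p = 0.0480 and 0.0487) and without a variance trend (0.0481 for each), heat shock also with no filter on low values (0.000748) and a term for replicate 1 (0.0317), and phosphate with array weights (0.00137). The remaining lists were not called: phenylpropanoid (camera adjusted p = 0.221), cysteine-rich receptor-like kinases (0.675), hypoxia (0.298), leaf senescence (0.278), cell cycle (0.740), the AT-hook motif family (0.880) and reference genes (0.880). The phenylpropanoid list was called higher without control replicate 1 or Pst hrcC replicate 2 (camera adjusted p = 0.000231 and 0.0153), and the hypoxia list lower without Pst hrcC replicate 1 (0.0115). Without the replicate 1 pair both were called (camera adjusted p = 0.0277 and 0.0294), as was the phosphate list (0.00365), and with no filter on low values the cysteine-rich receptor-like kinases were called higher (0.0376). Over all 6 libraries the adjusted p with an estimated correlation was 0.889 for phenylpropanoid, 0.785 for hypoxia, 0.425 for phosphate, 0.262 for heat shock and 0.917 for cysteine-rich receptor-like kinases. In limma no member of the heat shock, phosphate or remaining lists passed, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 1 phenylpropanoid, 2 senescence and 1 cell cycle genes were higher and 1 heat shock gene was lower. Seed storage and embryo markers reached at most 0.351 FPKM in any library, so none was tested.

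**Figure D2:**
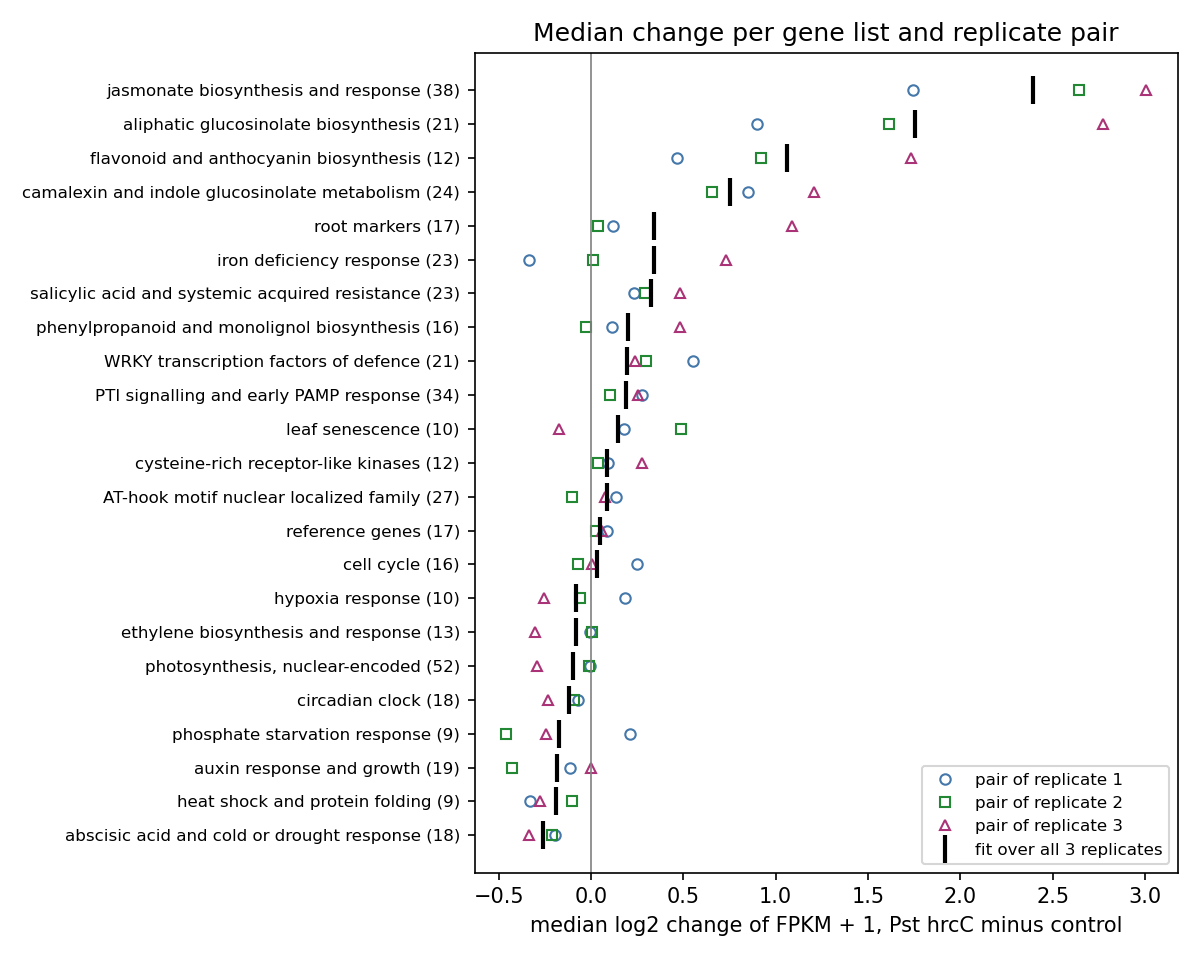
Median log2 change of each tested list (Pst hrcC minus control, FPKM + 1, number of tested genes in brackets) in the pairs of replicates 1, 2 and 3 (open symbols) and in the fit over all 3 replicates (black bars). The jasmonate list lies highest at 2.39, and its pair medians run from 1.74 to 3.00.

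Clock genes separated replicate 1 from replicates 2 and 3 in both groups. CCA1 (AT2G46830), a transcription factor that peaks at dawn, was at 14.5 FPKM in control replicate 1 and 16.0 FPKM in Pst hrcC replicate 1, and between 0.162 and 0.233 FPKM in the other 4 libraries. TOC1 (AT5G61380), which peaks in the evening, was at 6.28 and 6.58 FPKM in the replicate 1 libraries and between 46.3 and 66.9 FPKM in the others. Both genes were chosen after their values were seen. Of the 18 tested clock genes, 6 lay above both other replicates in both groups and 11 lay below, against 19.0% and 28.9% of all tested genes. Between the treatments no clock gene passed in limma, over all genes, adjusted over the list alone or at an unadjusted p under 0.05: PRR7 (AT5G02810) differed by -0.31 ± 0.17 and GI (AT1G22770) by -0.35 ± 0.52 on the log2 scale (SE, limma adjusted p = 0.930 and 1.00). The list was not called (camera adjusted p = 0.153), and was called lower with the replicate block (camera adjusted p = 0.00285; adjusted p = 0.477 with the block and an estimated correlation). It was also called lower without Pst hrcC replicate 2 (camera adjusted p = 0.0261) and without the replicate 1 pair (0.00365) or with a term for replicate 1 (0.00346).

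**Figure D3:**
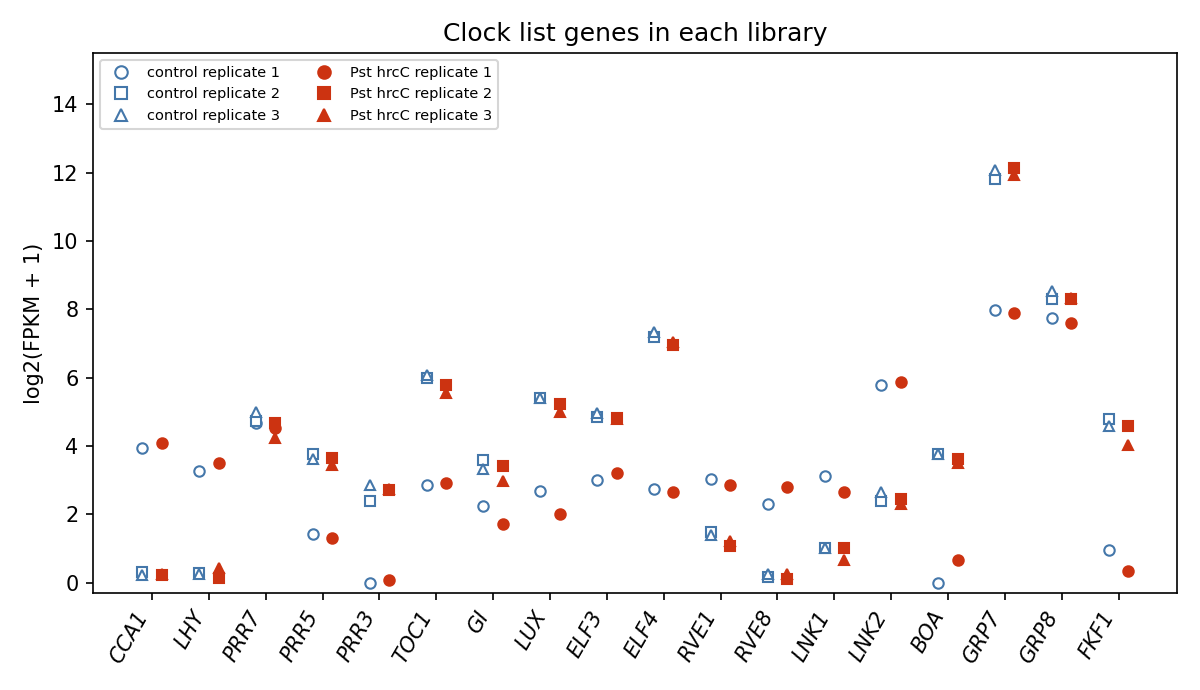
Level of each of the 18 tested clock genes, as log2(FPKM + 1), in every library, with controls as open blue and Pst hrcC libraries as filled red symbols and 1 symbol shape per replicate number. CCA1 is at 14.5 and 16.0 FPKM in the replicate 1 libraries and at most 0.233 FPKM in the others.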

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

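Leaving out the replicate 1 pair, a term for replicate 1, array weights and leaving out short genes were chosen after the data were seen; the other settings were fixed beforehand. The main test gave 49 changed genes, 48 of them higher. The number changed was 17 (16 higher) with a pseudocount of 5, 2 (2 higher) with no filter on low values, 101 (79 higher) after rescaling over nuclear genes, 2 (2 higher) at an adjusted p under 0.01 and 86 (82 higher) at one under 0.1. It was 182 (173 higher) without the replicate 1 pair, 129 (118 higher) with a term for replicate 1 and 407 (370 higher) with array weights. Leaving out 1 library gave between 2 and 180 (2 to 169 higher); these fits have 1 residual degree of freedom fewer. With the replicate block it was 47 (45 higher, 2 lower), of which 26 were among the 49. The cause of the other shifts was not tested.

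Camera called 8 lists higher and 3 lower. The number lower was 5 with a pseudocount of 5, 1 with a mean of at least 5 FPKM, 1 after rescaling over nuclear genes, 5 without a variance trend, 5 with the replicate block, 6 without the replicate 1 pair and 5 with a term for replicate 1, and 2 to 5 with 1 library left out. With an estimated correlation 0 were higher and 0 lower, and with fry 2 and 0. With an estimated correlation the adjusted p was 0.262 for pattern-triggered signalling and for WRKY factors, 0.240 for salicylic acid, 0.113 for jasmonate, 0.142 for camalexin and indole glucosinolates and 0.191 for aliphatic glucosinolates. With fry it was 0.128, 0.176 and 0.128 for the first 3 and 0.0567 for aliphatic glucosinolates. For pattern-triggered signalling it was 0.124 after rescaling over nuclear genes, and with 1 library left out it ran from 0.000512 to 0.0642. With the replicate block and an estimated correlation, the jasmonate, camalexin and indole and aliphatic lists were not called (camera adjusted p = 0.375, 0.375 and 0.437). These lists were called higher under all other settings run. Directions turned for photosynthesis without Pst hrcC replicate 3 (0.766) and for auxin without control replicate 1 (0.885), the highest with 1 library left out; the lowest were 1.0e-06 and 1.6e-06. The cause was not tested.

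Of the 9 named genes called changed, none turned direction in 179 comparisons with an alternative, and 61 of these no longer passed. Of the 47 not called, 31 of 917 comparisons passed and 2 turned sign. Among genes named by rule, the block ended the calls of PDF1.2a, NAS2, WRKY18 and SUR1, and it added those of the clock and heat shock lists. Among genes named after their values were seen, it ended those of LOX2, CORI3, OPR3, JAZ8, ST2A, AKN2 and AT5G17990, and added those of JAZ2, ANAC055 and IGMT1. It changed no other call of a gene or list named in the text. Depth, which differed by up to 4.89 times from control replicate 1, limits low values most in control replicate 1 and Pst hrcC replicate 3.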

Other observations

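The tests of library depth, time of day for the jasmonate genes and root tissue, and both tests of the smaller rise in replicate 1 were chosen only after the results were seen. The gene families, and the genes named in this paragraph, were also chosen after the values were seen. Of the 49 changed genes 33 belong to no list, which does not place them outside the themes of the lists. Among them, JAL23 (AT2G39330) rose by 4.80 ± 0.50, MBP1 (AT1G52040) by 4.46 ± 0.54, AT1G52000 by 4.11 ± 0.44 and MBP2 (AT1G52030) by 2.56 ± 0.31 on the log2 scale (SE, limma adjusted p = 0.0363, 0.0461, 0.0379 and 0.0461). ASA1 (AT5G05730) and AT5G17990, both of tryptophan synthesis, rose by 1.46 ± 0.18 and 1.33 ± 0.16 (SE, limma adjusted p = 0.0461 for each), and AKN2 (AT4G39940), an adenylylsulfate kinase of sulfate activation, by 2.23 ± 0.27 (SE, limma adjusted p = 0.0461). With the replicate block AT5G17990 and AKN2 did not pass (limma adjusted p = 0.0623 and 0.0649). MBP1 and MBP2 are close paralogs, so their division of reads is uncertain. The family of mannose-binding lectins by product name, with 14 tested genes and a median of 0.21, was not called (camera adjusted p = 0.140, and 0.996 with an estimated correlation). Only 1 gene of that set rose in limma. It therefore does not hold all of JAL23, MBP1, AT1G52000 and MBP2, and does not test them as a group.

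Gene families by product name gave 255 sets of at least 10 tested genes. Camera called 5: defensins (11 genes, median log2 change 1.11), proline-rich extensins (14, 0.64) and MATE efflux proteins (31, 0.12) higher, and SAUR proteins (55, -0.20) and 3-ketoacyl-CoA synthases (14, -0.19) lower, each with an adjusted p of 0.00923. None held with an estimated correlation (adjusted p = 0.996 for each). No gene of the defensin set rose in limma, so PDF1.2a, PDF1.2b and PDF1.2c, which rose, are not in it.

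The clock genes that set replicate 1 apart may reflect harvest at another time of day. Of 13 morning-phased genes outside the clock list, 11 lay above both other replicates in both groups, and 3 of 3 evening-phased genes lay below, against 19.0% above and 28.9% below among all tested genes. A difference in library depth was argued against: the replicate 1 libraries differ in depth with 2 others between them, yet in 15 of these 16 genes outside the clock list both lay above or both below the other 4 libraries, where chance gives 13.3% and all tested genes gave 35.1%. Harvest times are not in the labels, so a shift in the plants' light schedule stays open, as does any other difference between plantings.

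The higher jasmonate genes after Pst hrcC were set against 3 technical explanations. A difference in time of day between the treatments would move clock genes about as much, yet the upper quartile of their absolute log2 changes was 0.28, below the jasmonate list's lower quartile of 1.17, although 9 of 18 were lower in all 3 pairs and they shifted by a median of 2.78 between replicate 1 and the others. Scaling between libraries would remove it under quantile normalization, where the median stayed at 2.31. More root tissue would raise root markers as much, yet their upper quartile was 0.58, also below 1.17. A response to the treatment is a candidate explanation that stays open, as do wetting, handling or wounding during spraying, since the labels do not say what controls received, and a difference from wild type was not tested. Within the treatment, microbial patterns were not told apart from other products of the strain.

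In 31 of 38 jasmonate genes the log2 change was smaller in pair 1 than in the mean of pairs 2 and 3. Over all genes 7 passed for the interaction of treatment and replicate 1, none of them in the jasmonate list and each listed at 0 in 4 or 5 libraries, and 762 had an unadjusted p under 0.05, where chance gives 846. A weaker inoculation or uptake stays open: the 11 tested genes of the VSP1 branch had a median difference of -1.49, while the 7 of the PDF1.2 branch had 0.61 but went both ways, with 3 smaller in pair 1 and no interaction passing. Time of day cannot be told apart from other features of replicate 1, since 1 pair alone was at that phase: the difference for VSP1 was -4.03 ± 0.38 on the log2 scale (SE, limma adjusted p = 0.200 for the interaction). The interaction fit had 1 library of each group in replicate 1, so its spread came only from replicates 2 and 3. Its SE, p-values and counts therefore hold no spread between pairs at the phase of replicate 1. No biological explanation was tested.

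Of the 10 splits of the 6 libraries into 3 and 3, 1 gave 49 or more changed genes, which was the real one, and the highest of the others gave 2. With 10 splits the share cannot be under 0.1, too few for a share under 0.05. The real split parts all 3 same-numbered pairs; the 3 others that do so gave 0, 0 and 2. The split of control replicates 1 and 2 with Pst hrcC replicate 1 against the rest gave 2667 genes at an unadjusted p under 0.05, against 1152 for the real one, which points to a structure among the libraries besides treatment.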
